A study of Mus musculus with 3 samples.

How the data were processed

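Single-cell RNA was measured in lung tissue from 3 groups of mice, with 1 library each: non-irradiated wild-type, irradiated wild-type, and irradiated conditional knockout with drug. The deposited matrices hold UMI counts per gene and cell barcode, made by the authors and not normalized. The file headers record software version 3.1.0 without naming the software, and the genome build is mm10 in the submitters' processing notes. Every listed barcode has at least 500 UMIs, so that filter was set upstream and shallower cells were not analysed here. The files list 31054 features, a dTomato sequence among them. Library totals were 85984536, 45800421 and 76667310 UMIs. For a class with 0 cells, 3 of the kept cells give 0.0262%, 0.0548% and 0.0334%.

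Cells with at least 500 UMIs, at least 250 genes and at most 15% UMIs from the 13 mitochondrial genes were taken. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5, and the top 0.8% per 1000 barcodes were removed, as planned. The automatic threshold would have marked 872, 3 and 216 cells. Of the cells that passed the filters, 12.4%, 5.67% and 9.03% were removed, and 25938 cells remained. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used with 15 neighbours, and the Leiden algorithm at resolution 1.5 gave 43 clusters of all libraries together, with no integration. Tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, with random seed 1.

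Markers of 34 cell classes, 34 gene lists, the alternatives and the rule for named genes were set before the data were examined, and 285 of 287 markers are in the files. The rule that turns markers into cluster names was set later. A cluster took the class with the most markers among its 50 leading genes, if at least 3 were there, at least 3 were detected in 10% of cells, no other class had more markers in the top 10, and the class belonged to the compartment with the most markers (at least 2) among the top 100. Clusters whose depth, multiplied by 3, was under the library median needed a marker of their class in the top 10. This named 24 classes and left 8 clusters as numbers. Compartments were planned as sums of named classes, but after the data were seen the numbered clusters were also counted, in the compartment with the most markers among their top 100 genes. Class names with the ending -like rest on these markers alone.

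For each class and library, UMIs were summed over cells and given as CPM. A gene counted as apart when its CPM ratio with 5 CPM added to both sides was at least 2 and the higher library had at least 30 UMIs. Classes needed 50 cells in each library, which 14 classes or clusters met, and the 5 classes described by rule are aerocyte-like, alveolar fibroblast-like, T-like, NK-like and B-like. Named genes are the 3 with the highest and the 3 with the lowest ratio per class and main pair among genes whose CPM reaches 20% of their highest class, leaving out mitochondrial, ribosomal protein, haemoglobin, clone-model, receptor-segment and Y-linked genes, Xist and Tsix, plus the 2 to 4 members with the largest log2 ratio of each list described. Genes of general capillary-like and AT2-like cells, of γδ T-like and adventitial fibroblast-like cells and of numbered clusters, Mid1 and Eif3j2 across classes, and Eif3j1 were picked after their values were seen, as were the values of single T-like clusters and the position of genes that pass the free RNA limit. Against 0 UMIs a fold is a lower bound computed with 3 UMIs.

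A gene list was summarised by the median log2 ratio of members with at least 20 UMIs over both libraries, by the number at least 1.5-fold higher or lower, and by its percentile among 10000 random lists of equal size matched on expression in 20 bins. The percentile describes a list and is not a test. Cell cycle shares were taken after thinning each cell to 1000 UMIs. For the position of the conditional knockout library, genes at least 2-fold apart were found with one part of an equal random split of the irradiated wild-type cells and measured against the other part. Cells were called female with at least 1 Xist UMI and no UMI of the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, and male with the reverse. Gene positions come from GENCODE vM21 on GRCm38, with all 114 identifiers found, and the overlap of Eif3j2 with Eif3j1 was counted in 31-base windows of their transcripts.

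The scoring was tested on simulated data, drawn from these counts with 200 genes set apart per class and pair. Class totals were drawn with Poisson error around a pooled profile, so differences between cells and between animals are not in the simulation. Genes 3-fold apart were recovered in 95% to 100% of cases and genes 1.5-fold apart were called in 0% to 3%. Genes with no difference were called in 0 cases in T-like, NK-like and B-like cells. In aerocyte-like cells it was 174 of 4677 between the wild-type libraries and 15 of 2281 between the irradiated libraries. Of 100 unshifted lists 2 to 7 fell outside the central 95%.

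Alternatives changed 1 choice at a time, except that equal thinned cells change the number of cells and the depth together: at least 1000 UMIs per cell, at most 5% mitochondrial UMIs, no doublet removal, Leiden resolution 0.8, each library clustered on its own, each cell named by its own marker score, cells weighted the same, median-of-ratios size factors, 20 CPM added, at least 100 UMIs in the higher library, equal numbers of cells thinned to 1000 UMIs, genes at least 1.5-fold apart, no thinning and at least 2 cell cycle UMIs. Restricting all libraries to female cells was added after seeing the data. It also drops cells without an Xist UMI, such as 2780 of 11469 non-irradiated cells with neither Xist nor Y-linked UMIs. That changes the number of cells and can change their depth, so its values do not show an effect of sex alone. Sequencing reads were not analysed here.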

Results

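Lung cells were profiled in 3 libraries of 10x 3' single-cell RNA counts, with 1 library per group: non-irradiated wild-type mice, irradiated wild-type mice, and irradiated conditional knockout mice treated with a drug. The libraries hold 85984536, 45800421 and 76667310 UMIs in 15485, 7084 and 11292 barcodes. After filtering 11469, 5476 and 8993 cells were kept, with a median of 4777, 5608 and 5975 UMIs per cell. Neither the knocked-out gene nor the drug is named in the labels, so the targeted gene could not be checked. The number of mice per library, the dose and the time after irradiation are not given in the sources used here. With 1 library per group there is no spread between animals and no test. Brackets hold 95% intervals, exact binomial for shares and exact Poisson for depth-scaled counts (CPM), and these cover counting error only.

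Endothelial and mesenchymal cells made up much less of the irradiated wild-type library than of the non-irradiated one, and lymphocytes much more. Endothelial-like cells were 1.53% (1.23 to 1.90) of kept cells after irradiation against 18.4% (17.65 to 19.07) without it. The ratio was 0.0836 (0.0674 to 0.104). Mesenchymal-like cells were 8.80% (8.07 to 9.58) against 36.7% (35.8 to 37.6), and lymphoid cells 80.1% (79.0 to 81.1) against 35.0% (34.2 to 35.9). Myeloid cells, at 5.48% against 6.20%, and epithelial cells, at 2.30% against 2.97%, differed less in share, and the interval of the myeloid ratio (0.775 to 1.007) includes no difference. Shares of a library depend on each other, so the higher lymphoid share by itself lowers all other shares. Cell numbers per lung were not measured, and these ratios are not the size of a loss of cells.

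The general capillary-like class, marked by genes such as Gpihbp1 and Sema3c, was 0.530% of the irradiated wild-type library (29 cells) against 13.8% (1587 cells). The gas-exchange capillary class that carries Car4 and Ednrb, here called aerocyte-like, was 0.913% against 2.62%. Lymphatic endothelial-like cells (Prox1, Mmrn1) numbered 74 in the non-irradiated library and 0 in both irradiated libraries, where 3 cells would be 0.0548% and 0.0334%. Alveolar fibroblast-like cells were 3.67% against 15.3%, adventitial fibroblast-like cells 1.68% against 6.17%, and the unnamed mesenchymal cluster 3, led by Saa3, Timp1 and Eln, 2.68% against 9.43%. Type 2 alveolar (AT2)-like cells were 0.347% against 1.962%, while type 1 alveolar (AT1)-like cells were 0.676% against 0.166%. The AT1-like cluster led with Ager, Cldn18 and Aqp5, but also with Krt8, Krt18, Krt7, Cldn4, Clu and Sprr1a of the transitional alveolar epithelial list. Its 37 irradiated cells had a median of 13148 UMIs and its 19 non-irradiated cells 631, so these shares may not compare like cells. Among leukocytes, nonclassical monocyte-like cells were 0.511% against 2.83%, and basophil or mast-like cells 1.42% against 0.0262% (3 cells).

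Within the lymphocytes, γδ T-like cells, which carry Trdc and Il17a, were 17.4% (16.4 to 18.4) of the irradiated wild-type library against 4.09% (3.73 to 4.47). NK-like cells were 17.0% against 5.96% and T-like cells 16.4% against 8.88%, whereas B-like cells were 10.8% against 12.7%. Among female cells with at least 3000 UMIs the differences in γδ T-like and NK-like cells were smaller, 15% against 5.86% and 11.65% against 6.78%, and T-like cells were 17.4% against 10.3%. The T-like class is the sum of 3 clusters that differed in direction. Cluster 2, led by Lef1 and Tcf7, held 221 irradiated and 699 non-irradiated cells. Cluster 6, with Cd28, Icos and Cd4, held 374 and 205, and cluster 8, with Cd8b1 and Cd8a, held 305 and 114. The γδ T-like class joins clusters 7, 10 and 12, with 364, 336 and 253 irradiated against 122, 234 and 113 non-irradiated cells. The lymphoid clusters 11 (Xcl1, Gzmc, Klrc1) and 13 (Tnfrsf4, Ctla4, Foxp3) met no naming rule and were 6.57% against 0.846% and 7.49% against 1.00%. Unnamed clusters together held 14.6%, 20.9% and 18.99% of the non-irradiated, irradiated wild-type and conditional knockout libraries.

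Several properties of the libraries run alongside these shares. Shallow clusters, with a median under 1000 UMIs, held 13.8% of non-irradiated cells, 2.995% of irradiated wild-type cells and 4.49% of conditional knockout cells. Cluster 4 of the alveolar fibroblast-like class (median 818 UMIs) supplied 861, 120 and 309 of its cells. Filtering on mitochondrial UMIs removed 13.05%, 9.51% and 8.99% of the barcodes. A fixed expected rate took 1622, 329 and 893 barcodes out as doublets, where the automatic threshold would have marked 872, 3 and 216. Cells of male type, with Y-linked and no Xist UMIs, were 27.85% of the irradiated wild-type library (1525 cells), against 1 cell in the non-irradiated and 25 cells in the conditional knockout library. Among cells of female type with at least 3000 UMIs, endothelial and mesenchymal cells together were 48.8% (47.7 to 49.97) without irradiation, 10.4% (9.24 to 11.6) in irradiated wild-type and 10.8% (10.1 to 11.6) in the conditional knockout library, and male cells of the irradiated wild-type library had 3.17% (2.32 to 4.21).

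**Figure D1:**
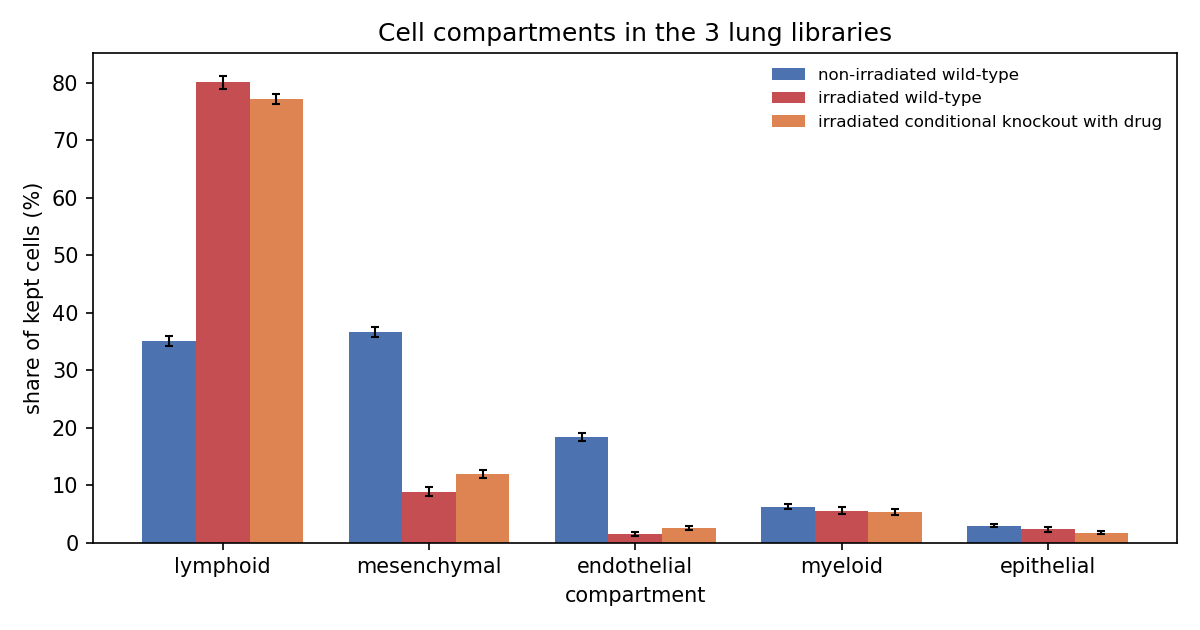
Share of kept cells per compartment in each library, with exact binomial 95% intervals that cover counting error only. Lymphoid cells were 35.0% of the non-irradiated, 80.1% of the irradiated wild-type and 77.2% of the conditional knockout library.

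Target genes of the tumour suppressor p53 were higher in endothelial and some mesenchymal cells of irradiated wild-type lung, and not in lymphocytes. In aerocyte-like cells 15 of 21 measured p53 targets were at least 1.5-fold higher and 1 lower than in non-irradiated cells (median log2 ratio 1.04, above all 10000 matched random lists). Cdkn1a, an inhibitor of cyclin-dependent kinases, stood at 1126 CPM (1009 to 1252) against 326 CPM (303 to 351), Trp53inp1 at 212 against 36.25 CPM, and Pmaip1, which promotes cell death, at 109 against 27.85 CPM. Gdf15, a secreted stress-response cytokine, stood at 539.7 CPM (460.0 to 629) against 18.1 CPM (13.01 to 24.6), in 15 of 50 irradiated cells. Of these UMIs 57.7% lay in 3 cells. In adventitial fibroblast-like cells 11 of 23 targets were higher and 2 lower (median 0.58), among them Eda2r at 56.5 against 12.2 CPM and Ccng1 at 145 against 41.9 CPM. That list was no longer outside the central 95% of random lists when all cells weighed the same (median 0.36).

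In cluster 3, 8 of 25 p53 targets were higher and none lower (median 0.48), with Cdkn1a at 333 (309 to 358.5) against 95.7 CPM (90.1 to 102) and Mdm2, which degrades p53, at 109.7 against 49.9 CPM. General capillary-like and AT2-like cells, with only 29 and 19 irradiated cells, had list medians of 1.39 (15 of 22 higher, 1 lower) and 0.69 (14 of 22 higher, 1 lower). In alveolar fibroblast-like cells the median was 0.11, at percentile 85.9. The list lay at 0.14 in T-like, -0.05 in NK-like and -0.24 in B-like cells. Cdkn1a lies on chromosome 17 (ENSMUSG00000023067, GRCm38) and Gdf15 on chromosome 8 (ENSMUSG00000038508).

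Interferon-stimulated and matrix genes were also higher in some mesenchymal cells after irradiation. In adventitial fibroblast-like cells 20 of 22 type I interferon-stimulated genes were at least 1.5-fold higher and none lower (median log2 ratio 1.08), with the transcription factor Irf7 at 44.9 against 11.8 CPM, seen in 12 of 92 irradiated cells, and Lgals3bp at 141 against 47.0 CPM. In cluster 3, 12 of 24 were higher and none lower (median 0.62), led by Isg15 at 100.8 (87.9 to 115) against 30.5 CPM (27.4 to 33.9) and Ifit1 at 28.8 against 8.82 CPM, seen in 44 and 17 of 147 irradiated cells. The extracellular matrix and fibrosis list was higher in adventitial fibroblast-like cells (15 of 26 higher, 2 lower, median 0.61), with the collagens Col6a3 at 767 against 322 CPM and Col15a1 at 384 against 185 CPM, while Acta2, the smooth muscle actin, was lower at 114.5 against 297 CPM. Cthrc1, a collagen-associated secreted protein, had 0 UMIs against 39 in 18 of 708 cells, at least 1.686-fold lower. In cluster 3 and alveolar fibroblast-like cells the matrix medians were 0.24 and 0.14, and both lists lay inside the central 95% with female cells only. Alveolar fibroblast-like cells had Eln, which encodes elastin, at 1438 (1351 to 1529) against 536 CPM (518 to 555), Cpxm1 at 161 against 64.5 CPM and Egr1, an immediate early transcription factor, at 690.5 against 305 CPM. Lower there were Eva1a at 1.415 CPM (1 UMI, 0.0358 to 7.88) against 13.3 CPM (10.6 to 16.5), Gng8 at 11.3 against 39.7 CPM, and Saa3, an acute phase protein that also defines one of its clusters, at 94.8 against 332 CPM.

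Plvap, Hey1 and Mcf2l were the genes named by rule as lower in aerocyte-like cells of irradiated wild-type lung. Plvap, which forms the diaphragms of endothelial pores, stood at 49.7 CPM (27.8 to 81.9) against 569 CPM (539 to 601), and Hey1, a Notch target, at 3.31 CPM (1 UMI, 0.0838 to 18.45) against 87.1 CPM (75.4 to 100.1). Mcf2l had 0 UMIs against 58.4 CPM, at least 5.875-fold lower. Without doublet removal the log2 ratios of Mcf2l and Hey1 were only -0.32 and -0.25. The capillary endothelial identity list had 3 of 20 higher and 8 lower (median -0.25) and lay inside the central 95% of random lists, and among its members the receptors Tek, Kit and Aplnr stood at 56.3 against 368, 39.7 against 239.6 and 6.62 (2 UMIs, 0.802 to 23.9) against 57.9 CPM. Plvap, Kit and Aplnr also mark general capillary-like cells, of which there were 29 against 1587, and the endothelial gene Cldn5 was at least 2-fold lower in 11 of 14 classes, so these values hold an unknown part of free RNA or doublets. Hypoxia and glycolysis genes were higher, 10 of 15 with 1 lower (median 0.91), such as Ankrd37 at 162 against 23.9 CPM and Ldha at 291 against 112 CPM, whereas Vegfa was lower at 52.98 against 215 CPM. Ltc4s, the leukotriene C4 synthase, at 116 against 1.77 CPM, and the imprinted gene Mest, at 175.5 against 22.1 CPM, came from 10 and 9 of 50 cells, and 54.7% of the Mest UMIs lay in 1 cell.

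Lymphocytes of the irradiated wild-type library carried less Klf2, and γδ T-like and B-like cells more interferon-γ-induced transcripts. In the T-like class as a whole 8 of 15 cytotoxic genes were higher and 1 lower (median log2 ratio 0.70), with the receptor Klrk1 at 48.8 against 16.1 CPM and the transcription factor Tbx21 at 17.9 against 5.53 CPM. This went with the mix of clusters, since cluster 2, led by Lef1 and Tcf7, was 24.56% of irradiated and 68.7% of non-irradiated T-like cells, and cluster 8 33.9% and 11.2%. Taken one by one, which was done after the values were seen, clusters 2, 6 and 8 had cytotoxic medians of -0.41, -0.40 and 0.09. The T-like class also had higher Klrc2 (44.7 CPM, 39.6 to 50.3, against 8.37 CPM, 6.32 to 10.9), Tnfsf11, the ligand RANKL (35.5 against 8.37 CPM), and Ikzf2, a transcription factor of regulatory T cells (113 against 35.4 CPM), and their log2 ratios were 0.09, 0.57 and -0.30 within cluster 2, 1.48, 1.08 and 0.70 within cluster 6 and 0.79, 0.79 and 0.69 within cluster 8. Its inhibitory receptor list had 6 of 13 higher and none lower (median 0.45), and this was lost with 20 CPM added and stayed outside the central 95% only in cluster 6. Bcl3 (18.1 against 66.7 CPM), Cdkn2d (42.0 against 132 CPM) and Ly6k (6.46 against 26.9 CPM) were lower in the class. Within clusters 2, 6 and 8 the log2 ratios were -1.34, -0.42 and -1.34 for Bcl3, -1.49, -1.17 and -0.54 for Cdkn2d, and -1.16, -0.71 and -0.29 for Ly6k. Interferon-γ-induced genes were higher in γδ T-like cells (11 of 19, none lower, median 0.67), with Igtp at 52.5 against 17.1 CPM and Tgtp2, which has a near-identical copy, at 15.3 against 2.40 CPM. They were also higher in B-like cells (7 of 16, none lower, median 0.44), where Irf1 stood at 627.6 (599 to 657) against 246.5 CPM (235 to 259). Serpina3f at 23.2 against 3.16 CPM and Sag at 26.5 against 9.32 CPM were the other genes named higher in B-like cells, seen in 38 and 53 of 592 cells, and the log2 ratio of Sag was 0.62 with female cells only. The γδ T-like values of this pair do not separate expression from mix, since cluster 10 was 35.3% of irradiated and 49.9% of non-irradiated cells of the class.

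Klf2, a transcription factor of resting lymphocytes, stood at 768 against 1880 CPM in T-like, 721.5 against 1665 CPM in B-like and 172 against 551 CPM in γδ T-like cells, and its log2 ratio was -0.75, -1.29 and -1.03 within T-like clusters 2, 6 and 8. The naive and central memory list that holds it was lower in T-like cells (0 of 12 higher, 2 lower, median -0.41), again with the mix of clusters (0.03, -0.37 and -0.01 in clusters 2, 6 and 8), and in γδ T-like cells (1 higher and 5 lower of 11, median -0.58). Heat shock and dissociation stress genes were lower in B-like (median -0.48), NK-like (-0.44) and γδ T-like cells (-0.53), with Fosb at 154 against 532 CPM and Socs3 at 55.0 against 196 CPM in B-like cells. Lmna, the nuclear lamin A/C gene, was lower in B-like cells at 35.9 against 134 CPM. NK-like cells had less Pdgfa (35.6 against 93.5 CPM), Hic1 (12.5 against 33.3 CPM) and Utf1 (23.1 against 55.0 CPM), and more Cfap46 (34.5 against 10.1 CPM), although the log2 ratio of Utf1 was -0.11 in equal thinned cells. Their Hspa1b, at 169 against 20.3 CPM, and Hspa1a, at 149.9 against 34.15 CPM, came from 84 and 80 of 930 cells, and reads cannot be placed with certainty between these near-identical chaperone genes.

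Free RNA differed between the same libraries and bears on every lymphocyte value. Sftpc, a surfactant gene of type 2 cells, stood at 919.6, 50.7 and 59.4 CPM in T-like cells of the non-irradiated, irradiated wild-type and conditional knockout libraries and at 1325, 54.7 and 82.8 CPM in B-like cells. Sftpa1, Sftpc and Scgb1a1 were at least 2-fold lower after irradiation in 14 of 14 classes. At least 2-fold higher and lower genes numbered 72 and 151 in T-like, 17 and 164 in NK-like, and 6 and 209 in B-like cells. They were 45 and 16, 14 and 4, and 6 and 9 once genes at under 20% of their highest class were set aside. The median of all tested genes was 0.17, 0.16 and 0.09 (log2) in these classes. With median-of-ratios scaling T-like cells had 35 higher and 197 lower, 15.1% higher in place of 32.3%. With equal numbers of cells thinned to 1000 UMIs the splits turned round, to 134 and 44 in T-like, 64 and 39 in NK-like and 60 and 39 in B-like cells. Aerocyte-like cells had 90 higher and 473 lower genes and alveolar fibroblast-like cells 12 and 173. Simulated counts with no difference gave 174 of 4677 and 35 of 6671 genes. They hold counting error only, so they set no upper limit for calls that arise without a difference between groups. Equal thinned cells gave 18 and 28 genes in these classes, of which 7 and 7 were among those called with all cells.

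In the irradiated wild-type library, the myeloid cluster 19, led by Chil3, Spp1 and C1qb, differed in lipid-handling and inflammatory genes, which are described here after their values were seen. The cluster has 6 alveolar macrophage markers in its top 50 genes, but 2 interstitial against 1 alveolar macrophage marker in its top 10. Its median depth was 12026 against 4924 UMIs. Its values therefore do not separate expression from a mix of macrophage types. Lipid-associated macrophage genes were higher (9 of 17, none lower, median log2 ratio 0.70), with Gpnmb at 873 against 182 CPM and the fatty acid carrier Fabp5 at 2218 against 636 CPM, though 3 cells supplied 62.5% and 63.7% of their UMIs. Spp1, which encodes osteopontin and is a leading gene of the cluster, stood at 5063 (4931 to 5197) against 402 CPM (367 to 439), in 55 of 68 cells with 35.3% of the UMIs in 1 of them. NF-κB inflammatory genes were lower (20 of 22, 1 higher, median -1.23), with the chemokines Ccl7 at 9.08 against 161 CPM and Ccl2 at 39.1 against 401 CPM, from 23 and 29 of 156 non-irradiated cells. MHC class II genes were lower too (5 of 7, none higher, median -1.45), such as H2-Eb1 at 548 against 2814 CPM. In cluster 13 cytotoxic genes were higher (8 of 13, 2 lower, median 0.98), with Nkg7 at 73.55 against 10.3 CPM, and the inhibitory receptor Lag3 had 225 UMIs in 95 of 410 cells against 1 UMI (0.0373 to 8.21 CPM) in 115 cells.

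**Figure D2:**
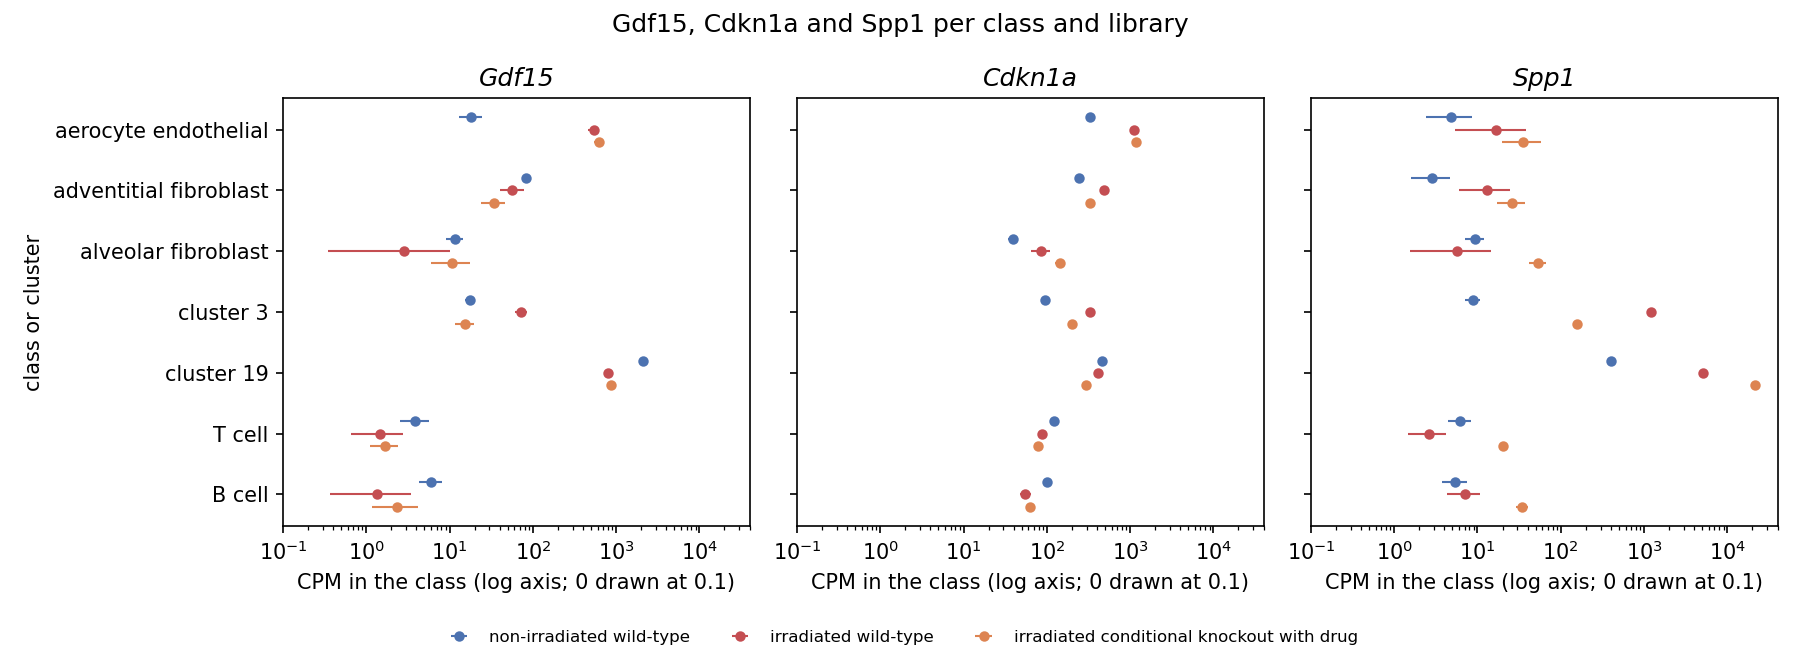
CPM of Gdf15, Cdkn1a and Spp1 per class and library, with exact Poisson 95% intervals for counting error only. In aerocyte-like cells Cdkn1a was 326, 1126 and 1190 CPM in the non-irradiated, irradiated wild-type and conditional knockout library.

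Relative to irradiated wild-type lung, the irradiated conditional knockout library with drug held more T-like and endothelial cells, and its endothelial, mesenchymal and lymphoid shares differed less than those of the wild-type libraries did from each other. Endothelial cells were 2.49% (2.18 to 2.83) against 1.53% (1.23 to 1.90), a ratio of 1.62 (1.27 to 2.08). Mesenchymal cells were 11.9% (11.2 to 12.6) against 8.80% (8.07 to 9.58), a ratio of 1.35 (1.22 to 1.496). Lymphoid cells were 77.2% against 80.1%, myeloid cells 5.30% against 5.48% and epithelial cells 1.75% against 2.30%. With female cells only, the mesenchymal ratio was 0.955 and the lymphoid ratio 1.04, on the other side of no difference, and with each library clustered on its own the endothelial ratio was 1.03. Within the classes, T-like cells were 23.6% (22.7 to 24.45) against 16.4% (15.5 to 17.4). Clusters 2, 6 and 8 held 808, 592 and 719 of 8993 kept cells against 221, 374 and 305 of 5476. Clusters 2 and 8 were thus a higher share of their library, and cluster 6 was not. Of the T-like class they made up 38.1%, 27.9% and 33.9% against 24.56%, 41.6% and 33.9%. NK-like cells were 12.3% (11.6 to 12.96) against 17.0% (16.0 to 18.0), cluster 13 3.81% against 7.49%, B-like cells 8.51% against 10.8%, and γδ T-like cells 18.8% against 17.4%. Among female cells with at least 3000 UMIs the NK-like shares were 11.1% (10.35 to 11.8) against 11.65% (10.5 to 12.9), and γδ T-like cells 21.8% (20.9 to 22.8) against 15% (13.7 to 16.4). General capillary-like cells were 1.18% against 0.530%, nonclassical monocyte-like cells 1.21% against 0.511%, and alveolar fibroblast-like cells 5.13% against 3.67%, with clusters 4 and 9 at 309 against 120 and 152 against 81 cells.

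Alveolar fibroblast-like cells and the mesenchymal cluster 3 of the conditional knockout library had fewer stress transcripts than those of the irradiated wild-type library, and several classes had more type I interferon-stimulated transcripts. In alveolar fibroblast-like cells 12 of 20 heat shock and dissociation stress genes were lower and none higher (median log2 ratio -0.76), with the immediate early factors Egr1 at 186 (164 to 210.0) against 690.5 CPM (631 to 755) and Fos at 264 (238 to 293) against 788 CPM (724 to 856), although the log2 ratio of Fos was -0.66 with cells weighted the same. In cluster 3 the count was the same, 12 of 20 lower (median -0.66), led by Junb at 923 against 1912 CPM. Adventitial fibroblast-like cells had 3 of 20 lower and 2 higher (median -0.17), which was lost with cells weighted the same. Type I interferon-stimulated genes were higher in B-like cells (8 of 20, median 0.55), γδ T-like cells (8 of 19, median 0.50), cluster 13 (10 of 22, median 0.42), alveolar fibroblast-like cells (5 of 19, median 0.34) and T-like cells (5 of 24, median 0.22), with none lower in these. The GTPase Ifi47 stood at 37.2 (31.9 to 43.1) against 12.1 CPM (8.46 to 16.7) in B-like and 78.6 against 33.6 CPM in γδ T-like cells, and Ifi27l2a at 80.75 against 26.8 CPM in γδ T-like cells. Cluster 10 was 28.0% against 35.3% of the γδ T-like class, so its values do not separate expression from the mix of clusters.

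The median of the matrix list was higher in cluster 3 (0.36), but only 4 of 26 members were at least 1.5-fold higher, and none lower. Tnc, tenascin C, stood there at 219.7 against 126 CPM. In alveolar fibroblast-like cells the median was 0.21, with only 2 of 23 members higher and none lower. Timp1, an inhibitor of matrix proteases, stood there at 151 against 60.8 CPM. The medians of all tested genes were 0.057 in cluster 3 and 0.087 in alveolar fibroblast-like cells. The alveolar fibroblast-like matrix list was lost with cells weighted the same. Alveolar fibroblast-like cells also had Saa3, which defines one of the clusters, at 633 (592 to 676) against 94.8 CPM (73.5 to 120.4) in 59 of 461 cells, and Parp12 (23.5 against 4.245 CPM, 3 UMIs) and Hmgn3 (21.4 against 4.245 CPM, 3 UMIs) higher, each with a second interval of 0.875 to 12.4 CPM. With female cells only the log2 ratio of Saa3 was 0.47 in place of 2.68. That setting drops every cell without an Xist UMI. In the conditional knockout library these were, over all classes, 1550 cells with neither Xist nor Y-linked UMIs and 25 of male type. It can thus remove shallow cells, and the lower value cannot be read as an effect of sex. With 1000 UMIs as the minimum the log2 ratio of Hmgn3 in alveolar fibroblast-like cells was 0.58 in place of 1.51. Galnt15 was lower there, at 17.1 against 53.8 CPM. In cluster 19, described after its values were seen, lipid-associated genes were higher again (8 of 17, 1 lower, median 0.48), with Ctsl, a lysosomal protease, at 4994 against 1216 CPM and Spp1 at 21226 (21017 to 21438) against 5063 CPM (4931 to 5197), in 103 and 107 of 129 cells. For each, 3 cells supplied 57.1% and 48.7% of the UMIs. The mix of macrophage types in this cluster was not separated from expression here either. Spp1 UMIs also stood at 20.15 against 2.58 CPM in T-like and 34.4 against 7.05 CPM in B-like cells.

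p53 targets did not differ in aerocyte-like cells between these irradiated libraries beyond random lists (median 0.09), where Cdkn1a was 1190 against 1126 CPM and Gdf15 618 against 539.7 CPM. They were lower in the few general capillary-like (106 against 29 cells, 9 of 19 lower, none higher, median -0.36) and AT2-like cells (34 against 19 cells, 8 of 13 lower, none higher, median -0.69), with Cdkn1a at 717 (646 to 795) against 1246 CPM (1061 to 1454) and 237 against 628 CPM. Of the latter UMIs 61.4% lay in 1 AT2-like cell. Cell cycle genes were higher in aerocyte-like cells (7 of 8, 1 lower, median 3.29), but from few cells. Cenpf, at 174 CPM against 0 UMIs (at least 17.55-fold), was seen in 4 of 74 cells with 68.0% of its UMIs in 1 cell. Mki67, at 83.7 CPM against 0 UMIs (at least 8.42-fold), was seen in 3 cells, and Top2a, at 72.1 CPM against 3.31 CPM (1 UMI, 0.0838 to 18.45), in 4 cells. Without doublet removal the log2 ratios of Cenpf, Mki67 and Top2a were 0.52, 0.52 and 0.46. Lower in aerocyte-like cells were Mest (39.5 against 175.5 CPM), Ggnbp2 (39.5 against 129 CPM) and Nptx1 (62.8 against 199 CPM). T-like cells had higher Gzmk, a granzyme, at 15.6 against 5.01 CPM, and Snhg9 at 34.8 against 14.4 CPM. In B-like cells Ly6k stood at 20.8 against 3.36 CPM and Rell1 at 17.4 against 52.35 CPM. NK-like cells had Alas2 at 18.5 CPM against 0 UMIs (at least 26.1-fold), a transcript of red cell precursors, in 9 of 1103 cells. The haemoglobin gene Hbb-bs stood there at 4590 against 52.9 CPM.

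Mid1 and Eif3j2 set the conditional knockout library apart from the irradiated wild-type library in most classes. Mid1, an X-linked ubiquitin ligase gene (ENSMUSG00000035299, chromosome X), was at least 2-fold lower in 12 of 14 classes (median log2 ratio -2.08). It stood at 31.2 (28.6 to 34.0) against 148 CPM (138 to 158) in T-like, 37.8 against 176 CPM in B-like and 33.55 against 108 CPM in NK-like cells. Eif3j2, which encodes a subunit of translation initiation factor 3 (ENSMUSG00000043424, chromosome 18), was at least 2-fold higher in 11 of 14 classes (median 2.23). It stood at 19.8 (17.7 to 22.04) against 1.78 CPM (0.887 to 3.18) in T-like, 35.9 against 2.685 CPM in B-like and 32.8 against 2.60 CPM in NK-like cells. Of the 31-base windows of its transcript 93.95% also occur in its near-identical copy Eif3j1 (ENSMUSG00000027236, chromosome 2), which was lower in 13 of 14 classes (median -0.58), so the Eif3j2 values are uncertain. The sum of both was 63.1 against 67.2 CPM in T-like and 110.6 against 114.5 CPM in B-like cells. In lymphocytes the peptide transporter Slc15a2 was lower, in T-like (4.70 against 27.3 CPM), B-like (7.43 against 40.6 CPM) and NK-like cells (7.255 against 35.2 CPM). So was Lars2 in T-like (341 against 869.5 CPM) and NK-like cells (352 against 913 CPM), next to Gm42418 at 1.76% against 3.06% of all UMIs. Gm42418 overlaps ribosomal RNA sequence and Lars2 differed along with it, so the Lars2 values are uncertain as expression of that gene. Genes at least 2-fold higher and lower numbered 7 and 14 in T-like, 10 and 8 in NK-like, 16 and 15 in B-like, 51 and 39 in aerocyte-like and 97 and 19 in alveolar fibroblast-like cells. With median-of-ratios scaling they were 10 and 6, 12 and 3, 29 and 6, and 75 and 25 in the first 4 of these classes, whose lymphocytes had a median of all genes of -0.11, -0.10 and -0.12. Equal thinned cells gave 9 and 84, 11 and 57, and 14 and 61 in T-like, NK-like and B-like cells.

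**Figure D3:**
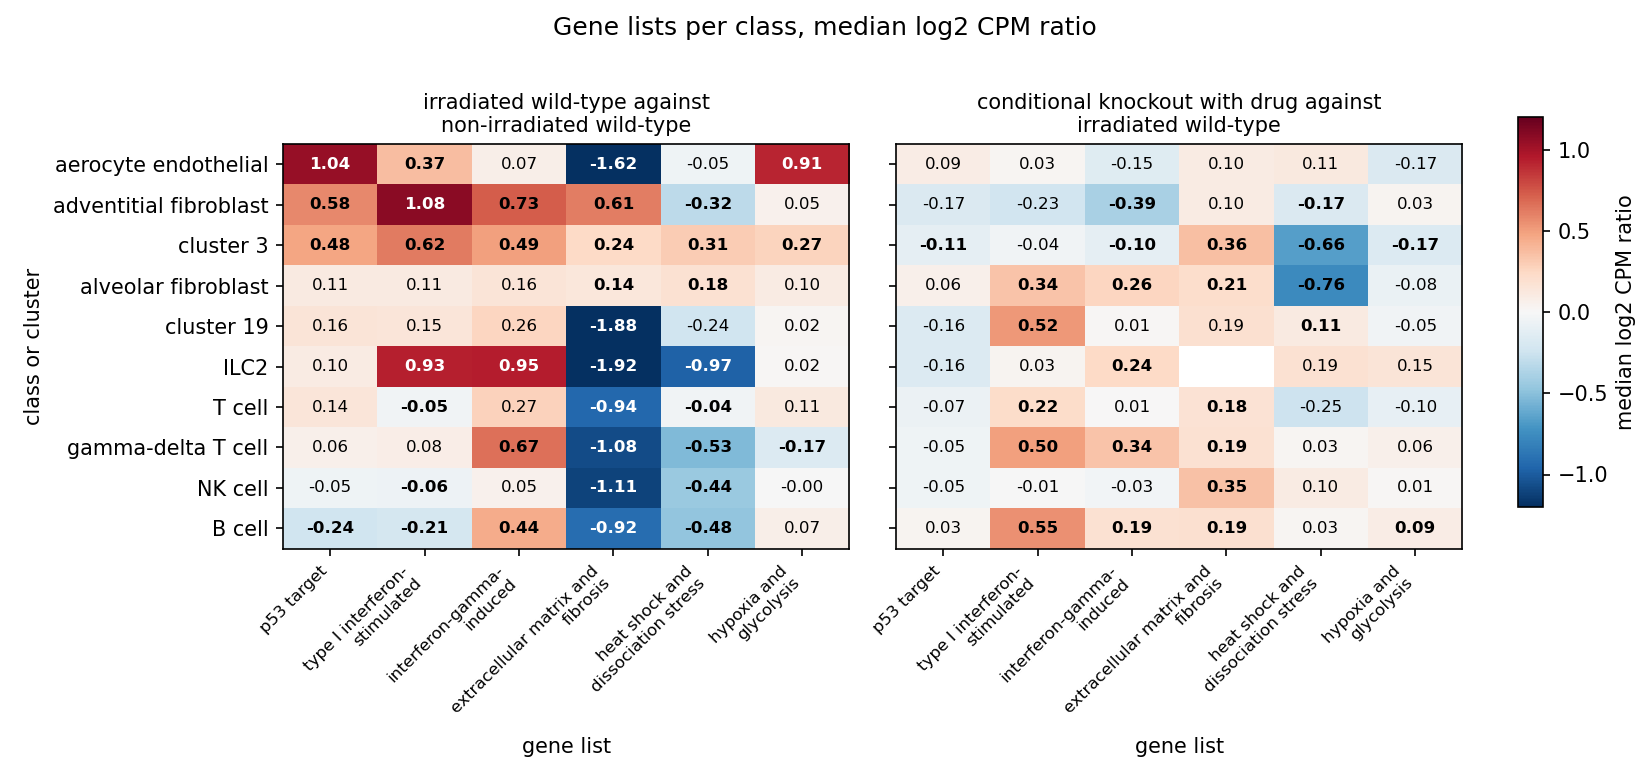
Median log2 CPM ratio of 6 gene lists in 10 classes or clusters for both pairs of libraries, bold where it lies outside the central 95% of matched random lists. Type I interferon-stimulated genes were higher in adventitial fibroblast-like cells of irradiated wild-type lung (1.08) and higher in B-like cells of the conditional knockout library (0.55).

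Genes higher after irradiation in T-like and NK-like cells of wild-type lung lay towards the non-irradiated level in the conditional knockout library more often than other genes. Among T-like cells this held for 87.9% of 91 genes higher and 74.7% of 150 genes lower after irradiation, against 62.9% and 37.1% of all genes. The mix of T-like clusters moved the same way, with cluster 2 at 68.7%, 24.56% and 38.1% of the class in the non-irradiated, irradiated wild-type and conditional knockout library, so the T-like values do not separate expression from mix. In NK-like cells it was 84.6% of 26 and 79.3% of 164 genes (61.3% and 38.7% of all), and in B-like cells 70.0% of 10 and 66.8% of 217 genes (61.5% and 38.5%). Most of the lower lymphocyte genes are candidates for free RNA. With genes at under 20% of their highest class set aside, 17, 2 and 7 lower genes were left in T-like, NK-like and B-like cells, 12, 2 and 6 of them towards the non-irradiated level, and for higher genes it was 54 of 59, 21 of 23 and 6 of 8. Aerocyte-like cells had 71.7% of 60 higher and 55.15% of 990 lower genes (49.0% and 50.8%), and alveolar fibroblast-like cells 26.3% of 19 and 62.3% of 377 (47.4% and 52.5%). Under the same limit for free RNA, aerocyte-like cells had 75% of 56 higher and 51.1% of 810 lower genes. Alveolar fibroblast-like cells had 33.3% of 12 and 56.1% of 221. The lower genes of aerocyte-like cells were then close to the share of all genes. The genes were found in one part of an equal random split of the irradiated wild-type cells and measured in the other part, but any deviation of that library as a whole enters both pairs and cannot be removed. The split leaves the mix of sexes in place too. Cells of male type were 27.85% of that library, against 1 cell in the non-irradiated and 25 cells in the conditional knockout library.

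Cells with at least 3 cell cycle UMIs after thinning to 1000 UMIs were 4.45% (4.06 to 4.87) of the non-irradiated, 10.4% (9.625 to 11.3) of the irradiated wild-type and 9.97% (9.34 to 10.6) of the conditional knockout library. The part owed to the mix of cell types was not computed. In NK-like cells the shares were 24.15%, 25.9% and 30.1%, in T-like cells 6.34%, 7.47% and 8.515%, in B-like cells 4.99%, 7.61% and 4.21%, and in alveolar fibroblast-like cells 0.257%, 0 of 129 cells (upper bound 2.82%) and 0.730%. Thinning left out 1294, 157 and 424 shallower cells, and free RNA can enter such counts. The class named by cycling markers was 0.462%, 1.64% and 1.21% of the libraries, and its main cluster also led with the granule genes Prtn3, Elane and Mpo.

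Compared directly with non-irradiated lung, the conditional knockout library held less endothelium (2.49% against 18.4%) and mesenchyme (11.9% against 36.7%). At least 2-fold higher and lower genes numbered 20 and 129 in T-like, 8 and 138 in NK-like, 26 and 199 in B-like, 54 and 305 in aerocyte-like and 76 and 84 in alveolar fibroblast-like cells. Over all lists and classes, 206 of 434 list medians lay outside the central 95% of random lists between the wild-type libraries. It was 131 of 433 between the irradiated libraries and 218 of 438 for this pair. Lists of genes drawn at random would give 21.7, 21.65 and 21.9. List members that vary together and differences between whole libraries also enter these counts, so the excess is not a test.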

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

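Except for the test of a few deep cells in aerocyte-like cells, the tests in this part were chosen after the result was seen. The test of male cells for the p53 targets used female cells only, a setting added after the data were seen.

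UMIs of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, which no comparison of cell types uses, numbered 4530 in the irradiated wild-type library and 59 in the conditional knockout library, against 8 in the non-irradiated library. They drew attention because the irradiated wild-type library also holds 23410 Xist UMIs, so that it contains cells of both sexes while the others are almost wholly female.

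The first pattern is the low joint share of endothelial and mesenchymal cells in the irradiated wild-type library, 10.3% against 55.0%. Male cells do not account for it, since female cells with at least 3000 UMIs had a share of 10.38% there against 48.8% in the non-irradiated library. Nor does the removal of listed barcodes by the filters: with every removed barcode of that library counted as endothelial or mesenchymal its share would be 30.69%, against 40.8% in the non-irradiated library with none counted. Shallow cells below the 500 UMI minimum of the files cannot be told apart from this pattern, because stricter filters, under which the highest ratio of either share was 0.228, only remove more cells. A lower recovery of tissue cells in dissociation may still contribute: the endothelial, mesenchymal and epithelial ratios differ by 9.29-fold, so that no single loss common to all tissue cells gives these shares, but a loss that differs between cell types cannot be told apart from irradiation, the biological candidate in the design, with 1 library per group. More lymphocytes would also lower this joint share, and shares alone do not separate that from fewer endothelial and mesenchymal cells.

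The second pattern is the higher level of p53 targets in aerocyte-like cells, adventitial fibroblast-like cells and cluster 3 of the irradiated wild-type library. Dissociation stress does not go with it in the first pair, where the higher median of stress genes was -0.0508, but in cluster 3 that median was 0.31, so stress may contribute there. A few deep cells do not account for the aerocyte-like value, 0.71 with all cells weighted the same, or for that of cluster 3, 0.36, but they could account for the adventitial one, which at 0.36 lay inside the central 95% of random lists. In adventitial fibroblast-like cells and cluster 3, male cells are argued against by the lower of the 2 medians in female cells alone, 0.41. Aerocyte-like cells were not part of that test. The Y-linked gene Ddx3y stood at 56.3 CPM in the irradiated wild-type aerocyte-like cells, against 26.1 CPM in adventitial fibroblast-like cells and 23.2 CPM in cluster 3. Male cells therefore remain open for the aerocyte-like value. In aerocyte-like cells a response to irradiation remains as a hypothesis, found and tested on the same data from 50 irradiated cells, and differences between animals were not tested.

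The third pattern is Mid1, lower, and Eif3j2, higher, in most classes of the conditional knockout library than of the irradiated wild-type library. Male cells do not account for Mid1, with a median log2 ratio of -2.57 in female cells alone. Free RNA from 1 of the 14 classes compared does not account for Eif3j2, whose highest class among them is 1.35 times the median class. Smaller classes were left out of that ratio, so it cannot exclude free RNA from 1 of those. Among them Eif3j2 was highest in basophil or mast-like cells of the conditional knockout library, at 50.6 CPM (27.0 to 86.6) from 13 UMIs. In AT2-like cells of that library it stood at 6.92 CPM. For Eif3j2 a candidate explanation is that reads moved between it and Eif3j1, through a sequence difference between the animals for example, because the sum of both genes had a median log2 ratio of -0.0905 while Eif3j1 was lower in 13 of 14 classes. For Mid1, strain or animal differences cannot be told apart from the knockout or the drug: between the wild-type libraries its median in female cells was 0.36, but male cells of the irradiated wild-type library, which carry neither, had a median of -1.74 against female cells of that library (44.95 against 219 CPM in T-like cells, with 31.3 CPM in female knockout cells). The gap between male and female cells may go with sex as well as with the animal, which these values do not separate. Whether Mid1 or Eif3j2 relates to the unnamed target was not tested.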

How the results depend on the processing

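No paired analysis was possible because each group has 1 library, and leaving out a library was not possible for the same reason. Numbered clusters have no value under settings that cluster the cells anew. Median-of-ratios size factors kept all 10 gene counts of the main classes within 1.5 times and 211 of 217 list calls, 20 CPM added kept 206. Weighting cells the same kept 177, with 39 weaker and 1 reversed, and female cells, a setting chosen after seeing the data, kept 174, with 38 weaker and 2 reversed. Leiden resolution 0.8 moved none of the 10 compartment ratios. Where no cause is named, the cause was not tested.

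For the compartment ratios of irradiated against non-irradiated wild-type (epithelial 0.776, endothelial 0.0836, mesenchymal 0.240, myeloid 0.884, lymphoid 2.29), naming each cell by its own score gave epithelial 0.594, endothelial 0.121 and lymphoid 2.355. Clustering each library alone gave endothelial 0.137 and mesenchymal 0.219, at least 1000 UMIs mesenchymal 0.219 and lymphoid 2.09, at most 5% mitochondrial UMIs myeloid 0.751, and no doublet removal lymphoid 2.51. Female cells gave epithelial 0.976, mesenchymal 0.277, myeloid 1.02 and lymphoid 2.01. For the conditional knockout against the irradiated wild-type library, clustering each library alone gave endothelial 1.03, mesenchymal 1.51 and lymphoid 0.848, at most 5% mitochondrial UMIs mesenchymal 1.13 and lymphoid 0.926, and own scores lymphoid 0.947. Female cells gave epithelial 0.514 and myeloid 0.740, and reversed mesenchymal to 0.955 and lymphoid to 1.04.

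Gene counts between the wild-type libraries in aerocyte-like, alveolar fibroblast-like, T-like, NK-like and B-like cells were 563, 185, 223, 181 and 215. They were 228, 32, 41, 44 and 45 with 20 CPM added and 191, 77, 133, 59 and 109 with at least 100 UMIs, both stricter by construction. Weighting cells the same gave 850 and 572 in the first pair of classes. No doublet removal gave 235 and 108, and 408 in B-like cells, at least 1000 UMIs 115 in alveolar fibroblast-like cells, and equal thinned cells, which are fewer and shallower at once, 18 and 28, with 103 in NK-like and 99 in B-like cells. Between the irradiated libraries the counts were 90, 116, 21, 18 and 31, and 48, 33, 3, 6 and 9 with 20 CPM added. In aerocyte-like and alveolar fibroblast-like cells at least 100 UMIs gave 6 and 22 and weighting cells the same 239 and 316, and no doublet removal gave 155 in the former. Equal thinned cells gave 10, 22, 93, 68 and 75, and female cells 38, 28 and 70 in T-like, NK-like and B-like cells.

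Single genes reversed mostly in classes with few carrying cells (log2 ratios). Between the wild-type libraries, Mgarp in adventitial fibroblast-like cells was -0.10 with at least 1000 UMIs, Plet1 in AT2-like cells 0.32 with that filter and 0.47 without doublet removal, and Fabp4 in general capillary-like cells -2.18, -1.64 and, in female cells, -2.225. Between the irradiated libraries, in adventitial fibroblast-like cells, Akr1cl was 0.11 and Mgarp 0.40 with at least 1000 UMIs, Mgarp 0.14 in female cells and Col11a1 -0.92 without doublet removal. Female cells gave 0.0701 for Angptl7 in cluster 3 and 0.85 for Saa3 in cluster 19, where equal thinned cells gave -2.115 for Il18bp. Among lists, naive T cell genes in general capillary-like cells were -1.01 in female cells between the wild-type libraries. Between the irradiated libraries MHC class II genes were 1.09 in cluster 19 with cells weighted the same and 0.70 in cluster 3 in female cells.

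The share of genes lower after irradiation that lay towards the non-irradiated level was 56.9% in alveolar fibroblast-like cells with genes at least 1.5-fold apart, and 58.65%, 94.9% and 74.4% in aerocyte-like, NK-like and B-like cells with 20 CPM added. Cells with cell cycle UMIs were 38.0%, 70.3% and 68.5% without thinning, where depth enters the share, and 12.6%, 23.2% and 23.5% with at least 2 UMIs.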

Other observations

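The reporter transcript dTomato was found in mesenchymal cells of all libraries. Its level there was 106 CPM (102 to 110.1) in the non-irradiated, 93.2 CPM (83.9 to 103) in the irradiated wild-type and 96.4 CPM (89.4 to 104) in the conditional knockout library, and 30.7%, 30.3% and 26.6% of mesenchymal cells had at least 1 UMI. Lymphoid cells, at 3.545, 2.12 and 1.90 CPM, had it in 1.92%, 1.255% and 1.15% of cells, at a median depth of 5032, 5532 and 5992 UMIs against 5228, 5808 and 4955 UMIs in mesenchymal cells. Endothelial cells stood at 4.04, 3.985 and 1.47 CPM and myeloid cells at 1.86, 0.2815 and 1.38 CPM. The labels do not say which allele carries the reporter.

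Within the irradiated wild-type library, cells of male and of female type differed in composition among cells with at least 3000 UMIs, a common minimum that does not match their depth. γδ T-like cells were 27.6% (25.3 to 29.97) of 1422 male and 15% (13.7 to 16.4) of 2660 female cells, and NK-like cells 19.5% (17.45 to 21.6) and 11.65% (10.5 to 12.9). Mesenchymal cells were 2.39% (1.66 to 3.325) of male and 9.29% (8.21 to 10.45) of female cells, whereas T-like cells, at 17.4% of both, and B-like cells, at 10.9% and 11.4%, were alike. A further 174 cells carried both Xist and Y-linked UMIs and 936 carried neither.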
